A study of Equus caballus with 40 samples.

How the data were processed

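Total RNA was measured in 40 samples of equine chondrocyte pellets, 4 in each of 10 groups formed by 5 treatments and 2 harvest times. Per the labels' protocols, 1 pellet from each group was homogenised, RNA was purified on silica columns with DNase treatment, and 100 ng of total RNA was amplified into biotin-labelled sense-strand cDNA for Affymetrix whole-transcript arrays. Per the submitters' processing notes, Affymetrix Expression Console, RMA and limma were used, with versions not stated. The deposited values were log2 expression values, 1 per probe set and array, of the kind RMA gives, which is a background-corrected, quantile-normalised and probe-summarised signal. How the submitters used limma, and the annotation they used, are not given in the sources used here. Normalisation across arrays sets the value distributions alike, so a shift of most transcripts in 1 direction would be reduced in these values.

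The table held 30559 probe sets for 40 arrays, and 0 columns belonged to no sample. Of these probe sets 17132 were listed with a gene in the platform annotation, 16789 with 1 symbol and 343 with several, and 13427 were unlisted and stay unnamed here. The 16789 probe sets gave 16661 genes, 111 of them with more than 1 probe set. Every probe set was tested, and only those with 1 symbol were named. A gene with several probe sets was represented by the one with the highest mean over the 40 arrays. SAA1 had 3 probe sets, which were all called higher with IL-1β at both times. No genome was used, so positions are not given.

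Groups and replicate numbers were taken from the sample titles. Comparisons were made with limma 3.58.1 in R 4.3.3, by a linear model with 10 group means fitted to all 40 arrays (30 residual degrees of freedom) and empirical Bayes moderation with an intensity trend (4.62 prior degrees of freedom). The model had no replicate term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. The 18 comparisons were IL-1β against control, each serum treatment against IL-1β and the serum treatments against each other at each time, and the differences of the IL-1β effect and the 3 serum effects between 48 h and 2 h. Every fold change is on the log2 scale, first group minus second.

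Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison, each with at least 5 measured genes. The lists covered cytokines and chemokines, NF-kB target and feedback genes, matrix degrading enzymes, protease inhibitors, cartilage matrix, chondrogenic regulators, fibroblastic and dedifferentiation genes, hypertrophy and mineralisation, prostaglandin and nitric oxide, immediate early genes, cell cycle, cholesterol and fatty acid synthesis, TGF-beta and BMP response, growth factors and IGF axis, interferon response, acute phase and complement, glucocorticoid response, hypoxia and glycolysis, oxidative stress defence and metallothioneins, unfolded protein and integrated stress response, the Wnt pathway and reference genes. They also covered markers of leukocytes, red cells and platelets, endothelium and mural cells, synovial fibroblasts, bone cells, and adipocytes and muscle. Of 504 list tests 103 passed with the preset correlation, and 34 of these held with an estimated correlation. The signs of median, mean and test differed in 0 of the 103.

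Genes named in the text followed a rule. For IL-1β against control and each serum against IL-1β, these were the 6 highest and 6 lowest log2 fold changes among called genes whose 4 arrays all lay on 1 side of the other group's mean. To them were added the 4 members with the largest moderated statistic of each list that passed camera or had at least a share of 0.2 of its members called, and 16 genes named in any case (IL6, CXCL8, IL1B, IL1RN, MMP1, MMP3, MMP13, ADAMTS4, ADAMTS5, TIMP1, PTGS2, NOS2, COL2A1, ACAN, COL1A1 and SOX9), of which 15 had a named probe set and IL1B had none. For the other comparisons the 3 highest and 3 lowest were taken. The design, lists, naming rule and alternatives were fixed before the data were examined, with 1 alternative added later.

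The alternatives were the replicate number as a fixed or random block, the upper 60% of probe sets by mean (18335), quantile normalisation applied again, arrays centred on their medians, no intensity trend, array weights, the spread taken only from the groups compared, a minimum of 1.5-fold, and each array or replicate number left out in turn. The alternative added later left out AES arrays 2 and 4 at 48 h. Each comparison of 4 with 4 arrays was also repeated over the 35 splits of its arrays, and each difference between times over 100 reassignments. Likeness of serum effects and return towards control were also computed with the IL-1β arrays divided into separate sets of 2 and on simulated unchanged groups. The simulation of shared calls and signs, and the split of the IL-1β arrays for shared calls, were added after the results were seen.

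The fit was tested on simulated data for ACS against IL-1β at 48 h, with 200 of 30559 probe sets changed. It recovered 15.5% of changes of 1.5-fold, 69% of 2-fold and 96.5% of 4-fold, with 2, 8 and 12 false calls and 0 wrong signs. The simulated noise was normal and independent between probe sets and between arrays. Deviations that probe sets or arrays share were left out, so these rates do not show how the fit behaves with them. The median residual SD was 0.269 on the log2 scale. No background level per probe set was used, so values near the lower end cannot be told from background.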

Results

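Expression was profiled in equine chondrocytes grown as 3D pellets, a culture form in which cartilage cells make their own matrix. Stimulated pellets received 5 ng/ml recombinant equine interleukin-1β (IL-1β), a cytokine of joint inflammation, for 48 h before treatment began. The groups that followed had IL-1β alone, IL-1β with autologous equine serum (AES), IL-1β with a treatment labelled AES24h, or IL-1β with autologous conditioned serum (ACS). The labels do not explain AES24h or give the serum doses. Control pellets had no IL-1β. Pellets were harvested after 2 h and 48 h, giving 10 groups of 4 arrays and 40 arrays in all. The array medians lay between 4.35 and 4.59 on the log2 scale, and values ran from 0.87 to 13.73. Arrays of 1 group correlated at 0.962 to 0.984 across probe sets, and any pair of arrays at 0.933 to 0.986. None of the 780 pairs of arrays held identical values. The labels do not say whether the 4 replicates of a group came from separate cultures or horses, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value given here.

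The first comparison set IL-1β against control at 2 h and asked what the cytokine does to the pellets. Collagenase and chemokine genes rose most. MMP1, the interstitial collagenase, had a mean of 11.41 ± 0.65 (SD, n = 4) with IL-1β and 2.95 ± 0.45 (SD, n = 4) in control, a log2 fold change of 8.46 (SE 0.47, adjusted p = 5.42e-15). The chemokines CXCL6 and CCL20 rose by log2 fold changes of 6.90 and 5.52. MMP3 (stromelysin-1) rose by 6.51, MMP13 (collagenase-3) by 5.24 and the decoy receptor IL1R2 by 4.95. At the other end stood genes of cell division, with ANLN at −4.48, PRR11 at −4.34, ASPM at −4.27, PRC1 at −4.23 and HMMR at −4.14, and the secreted factor ANGPTL7 at −4.04. All of these passed an adjusted p of 0.05 in limma. The control means of MMP1, CXCL6 and CCL20 and the IL-1β means of ANLN, PRR11, ASPM, PRC1 and HMMR lay below every array median and were not shown to be above background, so these differences give a direction and no exact fold or order among them.

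Inflammatory groups rose with IL-1β at 2 h. Of 22 measured cytokines and chemokines 8 rose and 0 fell (9 rose adjusted over the list alone, 10 members had an unadjusted p under 0.05 in limma, all higher, camera adjusted p = 5.31e-09), among them CXCL1 at 4.05 and IL6 at 4.08. Of 31 NF-kB target and feedback genes 13 rose (21 adjusted over the list alone, camera adjusted p = 1.39e-16), including BIRC3, an inhibitor of cell death, at 3.30 and TNIP3, a feedback inhibitor, at 2.08. The prostaglandin and nitric oxide list had 4 of 23 members higher (4 adjusted over the list alone, camera adjusted p = 0.00331). These were NOS2, the inducible nitric oxide synthase, at 4.03, the phospholipase PLA2G2A at 3.46, the prostaglandin E synthase PTGES at 1.55 and the receptor PTGFR at 1.46. PTGS2 (cyclooxygenase-2) had a log2 fold change of 1.58 (SE 0.72) and did not pass (adjusted p = 0.291). Acute phase and complement genes rose for 4 of 16 members (4 adjusted over the list alone, camera adjusted p = 6.91e-05), with the serum amyloid gene SAA1 at 3.99, the pentraxin PTX3 at 3.65 and complement factor B (CFB) at 3.64. Matrix degrading enzymes rose as a group (6 of 30 up and 2 down; 9 up and 3 down adjusted over the list alone, camera adjusted p = 6.46e-06), with the aggrecanase ADAMTS5 at 2.61. ADAMTS4 was at 0.73 and did not pass (adjusted p = 0.452). The control means of CXCL1, IL6, BIRC3, PLA2G2A and PTX3 lay below every array median and were not shown to be above background, so their differences give no exact fold.

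Genes of division, matrix and lipid synthesis fell at 2 h. Of 40 cell cycle genes 38 were lower with IL-1β (39 adjusted over the list alone; median log2 fold change −2.50, camera adjusted p = 7.23e-60), including the spindle checkpoint kinases TTK at −2.40 and BUB1 at −2.79. The IL-1β mean of 26 of the 40, TTK and BUB1 among them, lay below every array median and was not shown to be above background, so these values and the list median give a direction and no exact size. Of 33 cartilage matrix genes 8 fell (12 adjusted over the list alone, camera adjusted p = 5.31e-09), among them aggrecan (ACAN) at −1.86, the link protein HAPLN1 at −2.01 and collagen IX (COL9A1) at −1.59. COL2A1, the main cartilage collagen, was at −1.16 (SE 0.48) and did not pass (adjusted p = 0.221). Of 25 cholesterol and fatty acid synthesis genes 13 fell (20 adjusted over the list alone, camera adjusted p = 3.59e-16), for example CYP51A1 at −1.10 and ELOVL6 at −1.80. Unfolded protein and integrated stress response genes fell for 8 of 28 members (10 adjusted over the list alone, camera adjusted p = 9.63e-06), with MANF at −0.86. The fibroblastic and dedifferentiation list was lower by camera (1 of 30 up and 5 down; 3 up and 10 down adjusted over the list alone; adjusted p = 0.0175), but not with an estimated correlation (adjusted p = 0.39 with an estimated correlation). The glucocorticoid response list rose (3 of 18; 6 up and 1 down adjusted over the list alone, camera adjusted p = 0.00696), a call also lost there (adjusted p = 0.156 with an estimated correlation). The other 9 of the 11 lists past camera kept their call with an estimated correlation. SOX9, COL1A1, IL1RN and TIMP1 lay between −0.62 and 0.25 and did not pass.

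In all, limma called 1380 probe sets between IL-1β and control at 2 h, 476 higher and 904 lower. Without control replicate 1 the count was 874, and with array weights 2260. Of the 59 named genes past the threshold, 55 kept their call without any 1 array, and C7 (adjusted p = 0.0964 without control replicate 2), ANGPTL4 (0.238 without IL-1β replicate 1), ACTB (0.0638 without control replicate 3) and PPIA (0.205 without control replicate 1) did not. From 1 to 8 arrays each ended such a call, and the array with the highest adjusted p is given.

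**Figure D1:**
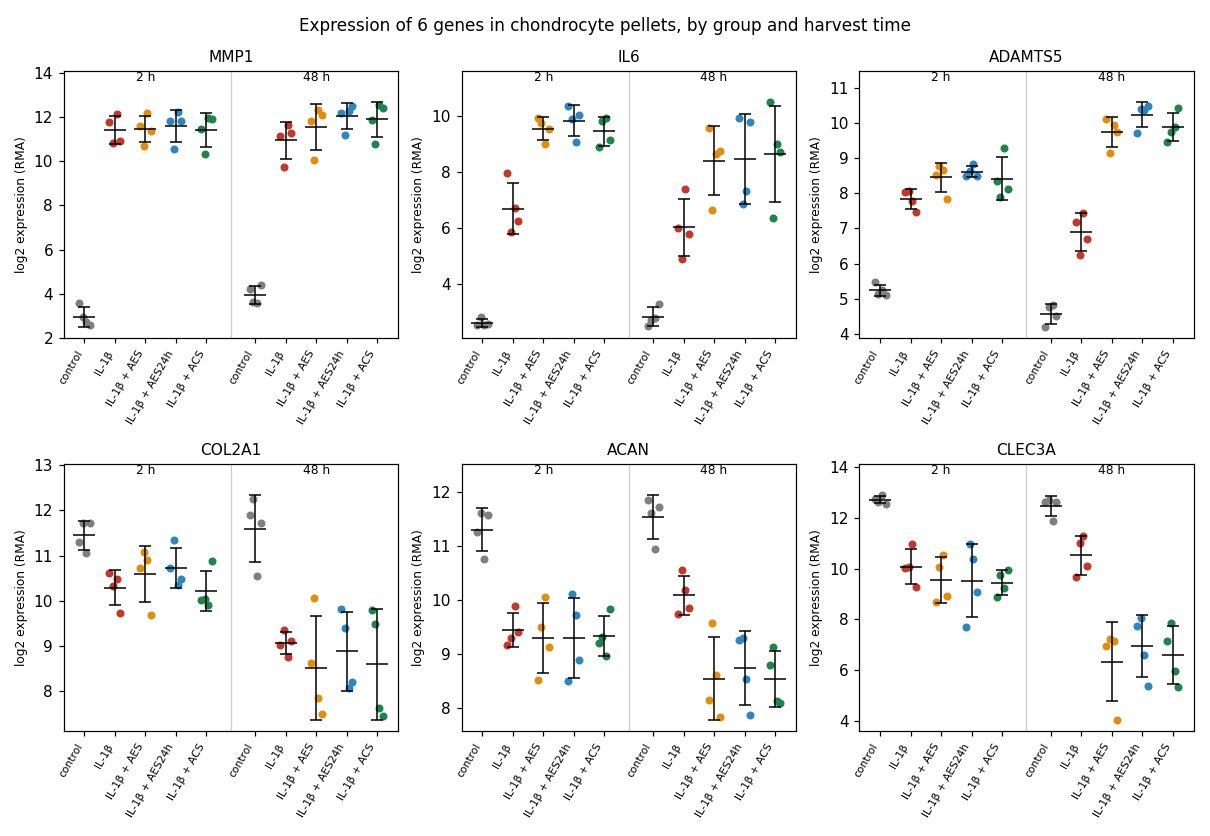
Log2 expression of MMP1, IL6, ADAMTS5, COL2A1, ACAN and CLEC3A on each of the 40 arrays by group and harvest time. Points are arrays, the horizontal line is the group mean and the bar is ± SD (n = 4); MMP1 averages 2.95 in the 2 h control and 11.41 with IL-1β at 2 h.

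The same comparison at 48 h showed raised collagenases and chemokines and lower cartilage matrix genes. CXCL6 had a log2 fold change of 7.25 (SE 0.50, adjusted p = 1.88e-12) and MMP1 had a mean of 10.95 ± 0.84 (SD, n = 4) with IL-1β and 3.95 ± 0.40 (SD, n = 4) in control (limma adjusted p = 8.85e-13). CCL20 rose by 5.34, C1H15orf48 by 5.07, MMP13 by 4.69 and MMP3 by 4.51. COL2A1 had a mean of 9.07 ± 0.24 (SD, n = 4) with IL-1β and 11.60 ± 0.74 (SD, n = 4) in control, a log2 fold change of −2.53 (adjusted p = 0.00174), and ACAN was lower by −1.45 (adjusted p = 0.0312). The lowest values were ANGPTL7 at −4.70, the transglutaminase F13A1 at −4.18, the matricellular gene POSTN at −3.32, NELL2 at −3.21, LOC100063831 at −2.87 and the actin-severing gene SCIN at −2.85. The control means of MMP1, CXCL6, CCL20, C1H15orf48, TNFAIP3, CXCL1, IL6, PLA2G2A and PTX3 lay below every array median and were not shown to be above background. The same held for the IL-1β means of F13A1, NELL2, LOC100063831, SCIN, CYTL1 and CD55. The differences of these genes give a direction and no exact fold or order among them.

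Of 33 cartilage matrix genes 13 fell at 48 h (18 adjusted over the list alone, camera adjusted p = 2.24e-20), including COL9A1 at −2.17, fibromodulin (FMOD) at −1.20 and CYTL1 at −1.29. Chondrogenic regulators fell as a group (1 of 16; 5 adjusted over the list alone, camera adjusted p = 0.00154), with CREB5 at −0.92, while SOX9 at −0.55 did not pass (adjusted p = 0.138). Cytokines and chemokines rose for 6 of 22 members (7 adjusted over the list alone, camera adjusted p = 4.51e-10), NF-kB genes for 11 of 31 (16 up and 1 down adjusted over the list alone, camera adjusted p = 1.31e-16), and prostaglandin and nitric oxide genes for 4 of 23 (4 adjusted over the list alone, camera adjusted p = 9.01e-06). NOS2 stood at 3.83, TNFAIP3, a brake on NF-kB signalling, at 2.11 and the RNase gene ZC3H12A at 2.03. CXCL8 at 2.36 did not pass (adjusted p = 0.111). Matrix degrading enzymes had 6 of 30 up and 1 down (8 up and 2 down adjusted over the list alone, camera adjusted p = 2.73e-05), and ADAMTS5 was at 2.32. Acute phase and complement genes had 3 of 16 up and 1 down (4 up and 1 down adjusted over the list alone, camera adjusted p = 2.73e-05), with SAA1 at 3.68 and the complement regulator CD55 at −0.70. Cholesterol and fatty acid synthesis genes fell for 14 of 25 members (18 adjusted over the list alone, camera adjusted p = 5.56e-23), such as LSS at −0.97 and HMGCS1 at −1.18.

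Limma called 0 of the 40 cell cycle genes at 48 h (0 adjusted over the list alone; 5 at an unadjusted p under 0.05, all lower). Their median was −0.54 with a camera adjusted p of 3.5e-06, a call not kept with an estimated correlation (adjusted p = 0.536 with an estimated correlation). The IL-1β mean of 11 of the 40 lay below every array median and was not shown to be above background, so this median is no exact size either. The camera call was lost in the same way for immediate early genes (1 of 32 lower, FOS at −1.47; 2 lower adjusted over the list alone, camera adjusted p = 0.0425; adjusted p = 0.536 with an estimated correlation) and for unfolded protein and stress response genes. In that list limma called 0 of 28 (0 adjusted over the list alone; 4 at an unadjusted p under 0.05, camera adjusted p = 0.0244; adjusted p = 0.366 with an estimated correlation). In all, limma called 386 probe sets at 48 h, 148 higher and 238 lower, with 252 called without control replicate 1, 244 without control replicate 4 and 757 with array weights. Of 38 named genes past the threshold 32 kept their call without any 1 array, the exceptions being ACAN (adjusted p = 0.135 without control replicate 1), FOS (0.18, control replicate 1), PTGFR (0.204, control replicate 1), CD55 (0.0618, control replicate 1), LOC100063831 (0.0572, control replicate 1) and CREB5 (0.223, control replicate 4). From 1 to 7 arrays each ended such a call, and the array with the highest adjusted p is given.

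The remaining fixed lists did not pass camera for IL-1β at 2 h. These were protease inhibitors (adjusted p = 0.914), chondrogenic regulators (0.123), hypertrophy and mineralisation (0.163), immediate early genes (0.558), TGF-beta and BMP response (0.329), growth factors and the IGF axis (0.584), interferon response (0.329), hypoxia and glycolysis (0.804), oxidative stress defence and metallothioneins (0.123), the Wnt pathway (0.914) and reference genes (0.21). Of 16 chondrogenic regulators 1 was lower (1 adjusted over the list alone). Of 29 TGF-beta and BMP genes 2 rose and 4 fell (4 up and 6 down adjusted over the list alone), with the BMP antagonist CHRDL2 at −1.39 and TGFBI at −1.45. Of 25 growth factor genes 3 rose and 1 fell (3 up and 1 down adjusted over the list alone), and of 28 Wnt genes 2 rose (3 up and 1 down adjusted over the list alone). Of 12 reference genes 1 rose (TFRC at 1.28) and 3 fell (1 up and 4 down adjusted over the list alone), including HPRT1 at −0.91 and ACTB at −0.59. Interferon response and oxidative stress genes had 1 member up each, of 29 and 18 (1 and 1 adjusted over the list alone). Of 31 hypoxia genes 1 rose and 1 fell (2 and 2 adjusted over the list alone), of 18 hypertrophy genes 2 fell (2 adjusted over the list alone), and of 32 immediate early genes 2 fell (2 adjusted over the list alone). Limma called 0 of the 12 protease inhibitors (0 adjusted over the list alone; 2 at an unadjusted p under 0.05).

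Markers of other cell types did not pass camera for IL-1β at 2 h. Camera gave adjusted p = 0.115 for leukocytes, 0.885 for red cells and platelets, 0.581 for endothelium and mural cells, 0.291 for synovial fibroblasts, 0.683 for bone cells and 0.943 for adipocytes and muscle. Of 12 endothelial and mural genes 2 fell (2 adjusted over the list alone). Limma called 0 of the 16 leukocyte, 7 red cell and platelet, 9 synovial fibroblast, 9 bone and 12 adipocyte and muscle genes (0 adjusted over each list alone). At an unadjusted p under 0.05 these lists held 1, 1, 1, 0 and 0 members.

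The effect of IL-1β differed between 48 h and 2 h for 1 gene. TK1, a thymidine kinase of DNA synthesis, had a difference of 1.64 (SE 0.27, adjusted p = 0.0196). Cell cycle genes differed as a list, with a median difference of 2.09 and 40 of 40 members positive (camera adjusted p = 5.36e-57; adjusted p = 0.0249 with an estimated correlation). Limma called 0 of the list's members over all probe sets and 38 adjusted over the list alone, and 1647 of all probe sets had an unadjusted p under 0.05. Many members had IL-1β means not shown to be above background (26 of the 40 at 2 h and 11 at 48 h), so 2.09 gives a direction and no exact size. The TK1 call was lost without any 1 of 9 arrays (highest adjusted p = 0.116, without control replicate 1 at 2 h). Limma called 3 probe sets with the spread taken only from the groups compared, and called 43 probe sets without control replicate 2 at 2 h and 85 with array weights.

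**Figure D2:**
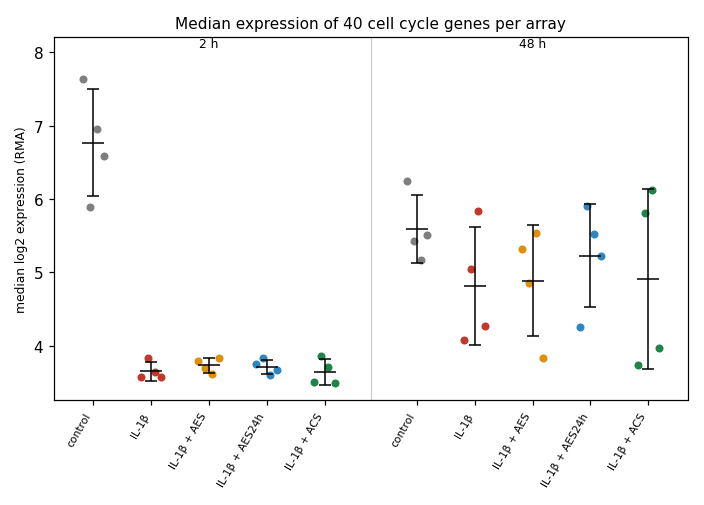
Median log2 expression of 40 cell cycle genes on each array by group and harvest time, with points for arrays, a line for the group mean and bars for ± SD (n = 4). At 2 h the control arrays lie between 5.89 and 7.63 and all arrays with IL-1β between 3.49 and 3.86.

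At 2 h, AES added to IL-1β raised 3 named genes against IL-1β alone. The nuclear receptors NR4A2 and NR4A1, which respond early to many stimuli, rose by 2.65 (SE 0.42, adjusted p = 0.00342) and 1.23 (SE 0.19, adjusted p = 0.00342), and the calcineurin regulator RCAN1 by 1.42 (adjusted p = 0.022). NR4A2 had a mean of 8.45 ± 0.70 (SD, n = 4) against 5.80 ± 0.91 (SD, n = 4). Immediate early genes rose as a group, with 2 of 32 called, 12 adjusted over the list alone and 31 positive (camera adjusted p = 2.16e-18; adjusted p = 0.00846 with an estimated correlation). Cytokines and chemokines and NF-kB genes were higher by camera (adjusted p = 0.000345 and 1.22e-05), calls not kept with an estimated correlation (adjusted p = 0.0694 and 0.0878 with an estimated correlation). Limma called 0 members of either list (1 and 4 adjusted over the list alone; 6 and 10 at an unadjusted p under 0.05). IL6 was at 2.86 (SE 0.66) and did not pass (adjusted p = 0.214).

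AES24h at 2 h raised 6 named genes. They were the transcriptional repressor PRDM1 at 1.60 (SE 0.23, adjusted p = 9e-04), the G protein regulator RGS16 at 1.55, UGCG (adjusted p = 0.0378), RCAN1 at 1.38, TBX3 at 1.34 and the NF-kB subunit REL at 1.16. NR4A2 was at 2.02 and IL6 at 3.15, and neither passed (adjusted p = 0.0873 for both). Limma called 0 of 32 immediate early genes (14 adjusted over the list alone, 15 at an unadjusted p under 0.05), and the list was higher with 30 positive (camera adjusted p = 3.16e-19; adjusted p = 0.00655 with an estimated correlation). NF-kB genes rose (1 of 31; 3 adjusted over the list alone, camera adjusted p = 1.12e-06; adjusted p = 0.0469 with an estimated correlation). TGF-beta and BMP genes rose by camera (adjusted p = 0.00448; adjusted p = 0.0469 with an estimated correlation), with 0 of 29 called by limma (1 adjusted over the list alone, 4 at an unadjusted p under 0.05). Higher by camera but not with an estimated correlation were cytokines and chemokines (adjusted p = 0.00372 and 0.091 with an estimated correlation), prostaglandin and nitric oxide genes (0.0465 and 0.0553) and hypoxia and glycolysis genes (0.000405 and 0.811). Limma called 0 members of these 3 lists (2, 1 and 0 adjusted over the list alone; 4, 2 and 2 at an unadjusted p under 0.05).

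ACS at 2 h raised 8 genes. NR4A2 rose by 2.94 (SE 0.42, adjusted p = 0.00101), NR4A1 by 1.30, FAM107B by 1.67, RGS16 by 1.53, TBX3 by 1.38, the transcription factor ETS2 by 1.34, RCAN1 by 1.31 and REL by 1.06. Immediate early genes rose (2 of 32; 9 adjusted over the list alone; 30 positive, camera adjusted p = 1.92e-19; adjusted p = 0.00613 with an estimated correlation). NF-kB genes (1 of 31; 4 adjusted over the list alone, camera adjusted p = 1.58e-07) and cytokines and chemokines (camera adjusted p = 9.27e-05) rose as groups, and both held (adjusted p = 0.03 and 0.03 with an estimated correlation). Unfolded protein and stress response genes rose slightly, with a median of 0.16 and 26 of 28 positive (camera adjusted p = 7.93e-06; adjusted p = 0.0464 with an estimated correlation). Synovial fibroblast markers were higher for 9 of 9 (camera adjusted p = 0.0321; adjusted p = 0.124 with an estimated correlation). Limma called 0 members of the last 2 lists and of the cytokine list (0, 0 and 1 adjusted over the list alone; 6, 0 and 5 at an unadjusted p under 0.05). IL6 was at 2.76 and did not pass (adjusted p = 0.276).

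Against IL-1β alone at 2 h, limma called 5 probe sets with AES (4 higher and 1 lower), 7 with AES24h and 8 with ACS (all higher). Without IL-1β replicates 1 to 4 the counts were 11, 3, 1 and 3 with AES, 18, 1, 1 and 1 with AES24h, and 16, 3, 2 and 4 with ACS. They were 1 without AES replicate 2, then 1, 4 and 1 without AES24h replicates 1, 2 and 4, and 2 and 4 without ACS replicates 2 and 3. With the spread estimated only from the groups compared, limma called 0 in each, with each array centred on its median 1 for AES24h and 4 for ACS, with array weights 9 for AES, and with no intensity trend 5 for ACS. Of the named genes past the threshold, 0 of 3, 1 of 6 and 2 of 8 kept their call without any 1 array. NR4A2 with AES had an adjusted p of 0.0611 without IL-1β replicate 3, and RGS16 of 0.277 with AES24h and 0.35 with ACS without IL-1β replicate 2. From 2 to 6, 5 to 6 and 2 to 7 arrays each ended such a call. MMP1, MMP3, MMP13, COL2A1, ACAN and NOS2 passed with none of the 3 sera at 2 h, where limma gave 2240, 1615 and 1595 probe sets with an unadjusted p under 0.05.

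At 48 h, AES raised the aggrecanase ADAMTS5 and lowered CLEC3A, COLGALT2, PSAT1 and ASNS. ADAMTS5 had a mean of 9.75 ± 0.42 (SD, n = 4) with AES and 6.89 ± 0.54 (SD, n = 4) with IL-1β alone, a log2 fold change of 2.85 (SE 0.26, adjusted p = 3.47e-08). The growth factor gene FGF7 rose by 2.60, FGL2 by 1.70 from an IL-1β mean not shown to be above background, CEMIP, which acts in hyaluronan breakdown, by 1.55, ANGPT4 by 1.53 and PDE7B by 1.52. CLEC3A, a lectin of cartilage, was at −4.18 (SE 0.65, adjusted p = 0.000669), the collagen galactosyltransferase COLGALT2 at −2.22, the integrin ITGA6 at −1.94 and the secreted glycoprotein STC2 at −1.74. PSAT1 (serine synthesis) was at −2.22 and ASNS (asparagine synthesis) at −2.10.

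Of 28 unfolded protein and integrated stress response genes 4 fell with AES at 48 h (9 adjusted over the list alone, camera adjusted p = 1.11e-07; adjusted p = 0.0214 with an estimated correlation). The members were ASNS, PSAT1, the amino acid transporter SLC7A5 at −1.16 and SEL1L at −0.49. Growth factor and IGF axis genes rose (1 of 25; 3 adjusted over the list alone, camera adjusted p = 0.0017; adjusted p = 0.00672 with an estimated correlation). Matrix degrading enzymes were higher by camera (3 of 30; 7 up and 2 down adjusted over the list alone; adjusted p = 0.00607; adjusted p = 0.187 with an estimated correlation), with ADAMTS7 at 0.88. Cartilage matrix genes were lower by camera (3 of 33; 4 adjusted over the list alone; adjusted p = 0.00548; adjusted p = 0.47 with an estimated correlation), namely HAPLN1 at −1.59, ACAN at −1.54 and COL11A1 at −0.92. Lists lost in the same way were cytokines and chemokines, higher (adjusted p = 0.00607 and 0.187 with an estimated correlation), immediate early genes, higher (0.00607 and 0.47), cholesterol and fatty acid synthesis, lower (0.000788 and 0.389), the Wnt pathway, higher (0.0147 and 0.331), and hypoxia and glycolysis, lower (0.00798 and 0.656), where P4HA2 fell by 0.67. Limma called 0 members of the first 4 (2, 2, 4 and 1 adjusted over the list alone; 3, 5, 8 and 5 at an unadjusted p under 0.05) and 1 of 31 hypoxia genes (1 up and 2 down adjusted over the list alone).

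Limma called 135 probe sets with AES at 48 h, 47 higher and 88 lower. The count was 25 without AES replicate 4, 69 without AES replicate 2, 328 without AES replicate 3, and 48, 30 and 71 without IL-1β replicates 1, 2 and 3. It was 230 with the upper 60% of probe sets, 223 with quantile normalisation again, 87 with centred arrays, 5 with the spread taken only from the groups compared and 14 without AES arrays 2 and 4, which had the highest array medians among the 4 AES arrays at 48 h and whose removal was chosen after seeing the data. Of 19 named genes past the threshold 7 kept their call without any 1 array. ACAN had an adjusted p of 0.242, HAPLN1 of 0.194, PSAT1 of 0.0865, SLC7A5 of 0.0966 and CEMIP of 0.052 without AES replicate 4, and FGF7 of 0.191 without IL-1β replicate 2. From 2 to 7 arrays each ended such a call.

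AES24h at 48 h raised ADAMTS5, IL11 and FGF7 against IL-1β alone. ADAMTS5 had a log2 fold change of 3.36 (SE 0.26, adjusted p = 3.87e-10), the cytokine IL11 of 3.45 (SE 0.62, adjusted p = 0.0055) and FGF7 of 3.26 (SE 0.57, adjusted p = 0.0052). The proteoglycan SRGN rose by 2.39, the G protein regulator RGS2 by 2.38, STAC by 2.22 and the lymphatic growth factor VEGFC by 2.05. CLEC3A was at −3.58, COLGALT2 at −2.11, STC2 at −1.68, EPCIP at −1.56, ITIH5 at −1.38 and PDZD2 at −1.16. Matrix degrading enzymes rose (5 of 30; 6 adjusted over the list alone, camera adjusted p = 3.79e-08; adjusted p = 0.00122 with an estimated correlation), including ADAMTS1 at 2.08 and the membrane collagenase MMP14 at 0.85. Growth factor and IGF axis genes rose (2 of 25; 4 adjusted over the list alone, camera adjusted p = 0.00016; adjusted p = 0.00118 with an estimated correlation).

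Calls lost with an estimated correlation for AES24h at 48 h were cytokines and chemokines, higher (1 of 22, camera adjusted p = 0.0321; adjusted p = 0.298 with an estimated correlation), NF-kB genes, higher (1 of 31; 0.00519 and 0.298), TGF-beta and BMP genes, higher (2 of 29; 0.00771 and 0.0882), and cartilage matrix, lower (1 of 33; 0.000172 and 0.298). These lists had 2, 4, 6 and 4 members adjusted over the list alone, and ID3, a BMP target, stood at 1.42. Higher by camera without a called member were cell cycle genes (40 of 40 positive; 5.3e-05 and 0.525 with an estimated correlation), immediate early genes (0.0251 and 0.503), cholesterol and fatty acid synthesis (0.00599 and 0.404), glucocorticoid response (0.00519 and 0.298) and oxidative stress defence (0.00337 and 0.298). In these 5 lists limma called 0 members (0, 0, 2, 4 and 0 adjusted over the list alone; 1, 6, 5, 7 and 5 at an unadjusted p under 0.05). The cell cycle median varied between arrays, at 4.08, 5.05, 5.84 and 4.27 on IL-1β replicates 1 to 4. In replicate 3 it lay above that with AES24h (5.52). In all, 69 probe sets passed, 50 higher and 19 lower, 27 with the spread taken only from the groups compared, 109 with the upper 60% of probe sets and 146 with array weights. The count was 17 and 41 without AES24h replicates 4 and 3, and 25 and 34 without IL-1β replicates 2 and 4. Of 20 named genes past the threshold 6 kept their call without any 1 array; without AES24h replicate 4, IL11 had an adjusted p of 0.0514, SRGN of 0.056, CLEC3A of 0.0596 and ADAMTS1 of 0.12. From 1 to 7 arrays each ended such a call.

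ACS at 48 h raised ADAMTS5, IL11 and FGF7 against IL-1β alone, with ADAMTS5 at 2.99 (SE 0.26, adjusted p = 9.58e-09), IL11 at 2.97 (SE 0.62, adjusted p = 0.0243) and FGF7 at 2.96 (SE 0.57, adjusted p = 0.0125). SRGN rose by 2.47, STAC by 2.35, FGL2 by 2.34 and the adhesion receptor VCAM1 by 2.12. The IL-1β mean of FGL2 and the ACS mean of INHBE were not shown to be above background. CLEC3A was at −3.94, COLGALT2 at −2.18, INHBE at −1.34, PDZD2 at −1.25 and MAMDC2 at −1.25. Growth factor genes rose (1 of 25; 3 adjusted over the list alone, camera adjusted p = 0.000211; adjusted p = 0.00109 with an estimated correlation), and so did matrix degrading enzymes (3 of 30; 7 up and 1 down adjusted over the list alone, camera adjusted p = 7.12e-06; adjusted p = 0.00801 with an estimated correlation).

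Other lists past camera with ACS at 48 h lost their call with an estimated correlation. Unfolded protein and stress response genes were lower (1 of 28, PHGDH at −1.13; 1 up and 4 down adjusted over the list alone, camera adjusted p = 0.00107; adjusted p = 0.163 with an estimated correlation). Cartilage matrix genes were lower (1 of 33, COL11A1 at −1.01; 3 adjusted over the list alone; 0.000604 and 0.336). NF-kB genes (1 of 31; 4 adjusted over the list alone; 0.00149 and 0.205), cytokines and chemokines (1 of 22; 2 adjusted over the list alone; 0.00316 and 0.109), TGF-beta and BMP genes (2 of 29; 5 adjusted over the list alone; 0.0174 and 0.107) and glucocorticoid response genes (1 of 18, KLF9 at 0.87; 4 adjusted over the list alone; 0.000466 and 0.107) were higher. For immediate early genes (0.0203 and 0.502) limma called 0 of 32 (1 adjusted over the list alone, 2 at an unadjusted p under 0.05). In all, 80 probe sets passed, 50 higher and 30 lower, against 50 and 18 with each array centred on its median, 1 in all with the spread taken only from the groups compared and 152 with array weights. The count was 27, 16, 36 and 29 without IL-1β replicates 1 to 4, and 45, 36 and 19 without ACS replicates 1, 3 and 4. Of 20 named genes past the threshold 7 kept their call without any 1 array; IL11 had an adjusted p of 0.125 without ACS replicate 1, VCAM1 of 0.287 without ACS replicate 4 and FGF7 of 0.102 without IL-1β replicate 2. From 3 to 7 arrays each ended such a call.

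At 48 h, 23 probe sets passed with all 3 sera, 13 higher and 10 lower, and each had a gene name. Higher were ADAMTS5, FGF7, FGL2, PDE7B, ATP6V0D2 (a proton pump subunit), CEMIP, ANGPT4, ITGB3, ID3, ANTXR1, NOX4, SH3PXD2B and CAMKK2. Lower were CLEC3A, COLGALT2, STC2, ITIH5, MAMDC2, GPT2, COL11A1, RNF19B, CYP24A1 and XYLT1, which acts in proteoglycan synthesis. AES24h and ACS shared 28 higher and 13 lower calls, where independent lists would share 0.0818 and 0.0187. AES shared 16 higher and 13 lower with AES24h, and 20 and 18 with ACS, against 0.0769 and 0.0547, and 0.0769 and 0.0864. These comparisons share their IL-1β arrays, which the independent expectation leaves out. In 100 simulations of unchanged groups with shared arrays, equally many top-ranked probe sets shared up to 22 higher and 7 lower (means 4.08 and 2.01) for AES24h and ACS, up to 16 and 15 (4.23 and 3.74) for AES and AES24h, and up to 15 and 14 (4.09 and 4.73) for AES and ACS. With the IL-1β arrays split into separate sets of 2, limma's calls shared 1 to 3 higher and 2 to 3 lower for AES24h and ACS, 1 to 3 and 2 to 3 for AES and AES24h, and 1 to 2 and 2 to 5 for AES and ACS. Fewer arrays also gave fewer calls, with 14 to 40, 24 to 70 and 21 to 59 probe sets called in either serum of these pairs, of which 85% to 100%, 77.1% to 95.8% and 85.7% to 94.7% had the same sign in both. Limma's own calls in the simulated unchanged groups shared at most 0, 1 and 0. MMP1, MMP3, MMP13, NOS2, PTGS2 and COL2A1 passed with none of the 3 sera at 48 h. COL2A1 lay between −0.56 and −0.19, and MMP1 between 0.62 and 1.09.

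**Figure D3:**
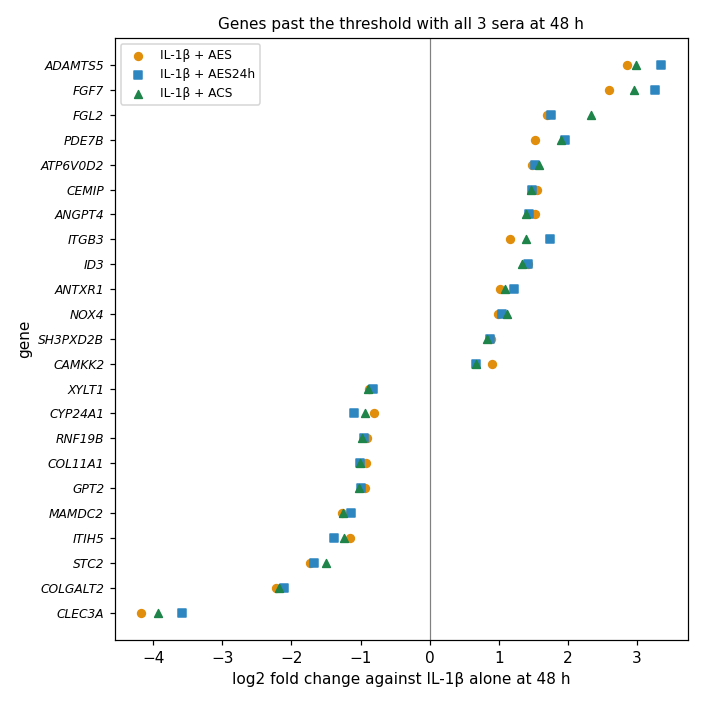
Log2 fold changes against IL-1β alone at 48 h of the 23 genes past the threshold with all 3 sera, with 1 point per serum. ADAMTS5 is at 2.85, 3.36 and 2.99 and CLEC3A at −4.18, −3.58 and −3.94 with AES, AES24h and ACS.

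The fold changes of 2 sera share the IL-1β arrays, which gives a correlation with no effect at all. At 48 h AES24h and ACS correlated at 0.71 across probe sets, AES and ACS at 0.516 and AES and AES24h at 0.463, where unchanged simulated groups gave 0.491 on average and 0.132 to 0.731 as the central range, so all 3 lay within it. The covariances were 0.0534, 0.0426 and 0.037 against 0.0329 in the simulation, whose range reached 0.065, above all 3. With the IL-1β arrays split into separate sets of 2 the correlations were 0.235, 0.127 and 0.0822. At 2 h they were 0.602 for AES and AES24h, 0.567 for AES and ACS and 0.558 for AES24h and ACS against 0.493 simulated (0.131 to 0.741), with covariances of 0.04, 0.0374 and 0.0346 against 0.0321 (up to 0.0677), all within the simulated range. With split arrays the correlations were 0.13, 0.102 and 0.0782. Probe sets are not independent replicates, so no p-value is given.

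Compared directly, the sera differed by 1 probe set without a gene name, lower with AES24h than with AES at 2 h (adjusted p = 0.0183), a call lost without any 1 of AES24h replicates 1, 3 and 4 or AES replicates 2, 3 and 4. At 2 h limma called 0 between ACS and AES and 0 between ACS and AES24h (1313 and 1197 at an unadjusted p under 0.05). Unfolded protein and stress response genes were higher with ACS than with AES (camera adjusted p = 0.00724; adjusted p = 0.88 with an estimated correlation) and than with AES24h (0.00431 and 0.465). At 48 h limma called 0 for AES24h against AES, ACS against AES and ACS against AES24h, with 3583, 3258 and 756 probe sets at an unadjusted p under 0.05. Without AES replicate 3 the first 2 counts were 134 and 44, and without AES replicate 1 the first was 10.

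Lipid and stress genes were higher with AES24h than with AES at 48 h by camera. Cholesterol and fatty acid synthesis genes had a median of 0.41 and 22 of 25 positive (8 adjusted over the list alone; adjusted p = 1.19e-09; adjusted p = 0.0889 with an estimated correlation), and unfolded protein and stress response genes 22 of 28 positive (9 adjusted over the list alone; 1.78e-06 and 0.0889). Oxidative stress defence (5 adjusted over the list alone; 0.000113 and 0.271), hypoxia and glycolysis (0 adjusted over the list alone; 0.000223 and 0.742), cell cycle (0; 0.00905 and 0.851) and reference genes (1, with 12 of 12 positive; 0.00978 and 0.28) were also higher. ACS was higher than AES for cholesterol and fatty acid synthesis (5 adjusted over the list alone; 1.23e-06 and 0.547), oxidative stress defence (0.0247 and 0.693), unfolded protein and stress response genes (0.0247 and 0.596) and reference genes (0.0339 and 0.547). ACS was lower than AES24h for cell cycle (0.000132 and 0.801), hypoxia and glycolysis (2.25e-05 and 0.801) and unfolded protein and stress response genes (0.000282 and 0.542). None of these list differences held with an estimated correlation. With ACS the cell cycle median was 3.74 and 3.96 on replicates 1 and 4, and 5.81 and 6.12 on replicates 2 and 3. With AES24h it was 4.26, 5.90, 5.52 and 5.23 on replicates 1 to 4.

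The serum effects at 48 h and 2 h differed for ADAMTS5 and RGS16. ADAMTS5 had a larger effect at 48 h with AES (difference 2.24, SE 0.37, adjusted p = 0.0235), AES24h (2.58, adjusted p = 0.00154) and ACS (2.42, adjusted p = 0.00537). RGS16 had a lower effect at 48 h with AES24h (−2.59, adjusted p = 0.0042) and ACS (−2.34, adjusted p = 0.0272). These differences exceeded its rise at 2 h, so its estimates at 48 h lay below IL-1β alone. Limma called no other probe set. With quantile normalization applied again the calls were 4 higher and 1 lower for AES, 2 and 1 for AES24h and 1 and 2 for ACS, and with centred arrays 1 and 0 for ACS. With the upper 60% of probe sets limma called 4 for AES and 6 for ACS, and with centred arrays 3 for AES. Without IL-1β replicate 1 at 2 h limma called 10 for AES. With the spread taken only from the groups compared limma called 0 for AES, 2 for AES24h and 0 for ACS. ADAMTS5 with AES was lost without any 1 of 7 arrays (highest adjusted p = 0.108, without IL-1β replicate 2 at 2 h) and RGS16 with ACS without any 1 of 11 (0.124, without ACS replicate 2 at 2 h).

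Whether a serum moved expression back towards control was asked by regressing the serum effect on the IL-1β effect across probe sets, with separate IL-1β arrays for the 2 effects. A slope of −1 would be a full return only if the IL-1β effect held no noise. That effect rested on 2 arrays of each group, and its noise pulls the slope towards 0 by an amount not estimated. Such noise shrinks a slope and does not by itself turn its sign. Slopes near 0 therefore do not exclude a return, while slopes above 0 give no sign of a return. At 48 h the mean slopes were 0.133 with AES, 0.0391 with AES24h and 0.0434 with ACS, and at 2 h 0.0073, 0.0056 and 0.031. Over the ways of dividing the arrays they ran from 0.0617 to 0.207, −0.0403 to 0.0793 and 0.0116 to 0.0767 at 48 h, and from −0.0079 to 0.0211, −0.0172 to 0.042 and −0.0072 to 0.0942 at 2 h, so the range crossed 0 for AES24h at 48 h and for all 3 sera at 2 h. For AES and ACS at 48 h the slope stayed above 0 in every division. The divisions reuse the same arrays, so these ranges are no sampling error. With shared arrays the slopes were −0.004, −0.17 and −0.151 at 48 h, and −0.0978, −0.112 and −0.0881 at 2 h. Unchanged simulated groups gave −0.494 at 48 h and −0.474 at 2 h. Their IL-1β effect was noise alone, so these slopes cannot be set beside the real ones. Covariances do not depend on that spread. They were −5e-04, −0.0191 and −0.017 at 48 h against −0.0329 simulated, and −0.0171, −0.0195 and −0.0154 at 2 h against −0.0308. Of the 386 probe sets called for IL-1β at 48 h, AES lowered 1 of the raised ones, AES24h 2 and ACS 3, and limma called 0 of the lowered ones higher with any serum. Independent lists would share 0.426, 0.092 and 0.145 of the former and 0.366, 0.389 and 0.389 of the latter, so these 0 counts show no lack of return. In the same direction as IL-1β, AES called 2 higher and 10 lower, AES24h 4 and 6, and ACS 5 and 3, where independent lists would share 0.228 and 0.685, 0.242 and 0.148, and 0.242 and 0.234. These counts use the same IL-1β arrays for both effects, which the independent values leave out. Sharing alone favours calls in opposite directions (correlation −0.492 in unchanged simulated groups at 48 h) and works against calls in the same direction. ADAMTS5, raised, and COL11A1 and COLGALT2, lowered, were called in the direction of IL-1β with all 3 sera, and RNF19B, raised by IL-1β, was called lower with all 3. COLGALT2 and RNF19B were chosen here after their IL-1β values were seen.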

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

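The fit without AES replicates 2 and 4 at 48 h was chosen only after the result was seen. For the other explanations tested here the criteria were written before the tests, but for patterns taken from the results.

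A single array stood apart from the other 3 of its group in 7 of 190 groups of 4 values (19 measures in each of 10 groups), where chance gives 9.5, since it marks about 1 in 20. At 2 h with ACS, COL2A1 was 10.87 in replicate 4 and 9.91 to 10.03 in the others, and MMP13 was 10.51 in replicate 2 and 12.19 to 12.51 in the others. NOS2 with IL-1β at 48 h was 10.45 in replicate 1 against 9.10 to 9.26. CXCL8 with AES at 48 h was 9.48 in replicate 1 against 6.93 to 7.07, and MMP13 there was 11.39 in replicate 2 against 12.64 to 12.85. ADAMTS5 with AES24h at 48 h was 9.71 in replicate 1 against 10.38 to 10.49. COL1A1 with ACS at 48 h was 9.56 in replicate 1 against 10.98 to 11.08.

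Differences between 48 h and 2 h passed limma's test for TK1 in the IL-1β effect (1.64), for ADAMTS5 in the effects of AES (2.24), AES24h (2.58) and ACS (2.42), and for RGS16 in those of AES24h (−2.59) and ACS (−2.34). Of 112 list differences between times 23 passed camera, and 3 of these held with an estimated correlation. Those 3 were cell cycle genes in the IL-1β effect (higher at 48 h, camera adjusted p = 5.36e-57) and unfolded protein and stress response genes in the effects of AES (lower, 5.85e-09) and ACS (lower, 8.04e-08). In the IL-1β effect, glucocorticoid response genes were lower (0.000225) and unfolded protein and stress response genes higher (0.0196). In the AES effect, matrix degrading enzymes (0.0059), glucocorticoid response (0.0411) and Wnt pathway genes (0.0411) were higher. Cartilage matrix (0.0411), immediate early (0.0018), cholesterol and fatty acid synthesis (0.0411) and hypoxia and glycolysis genes (0.00117) were lower. In the AES24h effect, matrix degrading enzymes (0.000236), cell cycle (0.0181), glucocorticoid response (0.0181) and oxidative stress defence genes (0.00209) were higher, and cartilage matrix (0.0234) and immediate early genes (0.000236) lower. In the ACS effect, matrix degrading enzymes (0.00634) and glucocorticoid response genes (0.0184) were higher, and fibroblastic (0.034), immediate early (0.000439) and hypoxia and glycolysis genes (0.034) lower.

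Cell cycle genes were far lower with IL-1β than in control at 2 h and less so at 48 h. A single array as the source is argued against, since at least 34 of the 40 members stayed called lower without any 1 of the 8 arrays, the fewest without control replicate 1. A change within the controls may contribute, as it needs: the members had a median change of −1.148 in control from 2 h to 48 h, with 40 of 40 lower. In the IL-1β group the median change was 0.926, with 39 of 40 higher, so both groups moved in direction. The IL-1β mean of 26 of the 40 at 2 h lay below every array median and was not shown to be above background, so 0.926 is no exact size to set beside the control change. Whether time in culture or handling at harvest lies behind the control change stays open and untested.

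The 23 genes called with all 3 sera at 48 h share their IL-1β arrays. The median change was 1.116 against the 2 h IL-1β arrays and 1.394 against the 48 h arrays, a ratio of 0.8, with 23 of 23 in the called direction. Whether the IL-1β arrays at 48 h stand apart is not decided by this. The 2 h arrays also differ from the serum arrays in harvest time, whose effect was not removed. A single IL-1β array at 48 h may decide part of the calls. With any 1 left out, at least 17 of 23 stayed called in at least 1 serum. From 8 to 14 stayed called in all 3, the fewest without replicate 2. No sign turned (0 of 23), and a test on fewer arrays has less power, which was not separated from the array itself. An effect that the serum treatments share stays open as a hypothesis.

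Sterol and fatty acid synthesis genes were lower with AES than with AES24h at 48 h, although limma called 0 single genes (3583 probe sets at an unadjusted p under 0.05). A trend with intensity is argued against as the whole cause, because with it removed the list median was 0.245 and lay above 100% of 10000 matched random lists (−0.107 to 0.125 for the central range), against 0.415 before. A single AES array is also argued against, since the median was at lowest 0.317 (76.5% of the full median) without replicate 4. No AES24h array was left out. The 2 groups overlapped, with a list median of 6.795 on AES replicate 3 and 6.679 on AES24h replicate 3. Reference genes were also higher with AES24h by camera, a call likewise lost with an estimated correlation. A shift of the AES arrays beyond this list is therefore not excluded. Without AES replicates 2 and 4, which have the highest array medians of that group, the difference had a list median of 0.223 with a camera adjusted p of 5.12e-07. The call of the sterol list did not hold with an estimated correlation, so correlation between the members may account for it. A difference between the sera stays open.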

How the results depend on the processing

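The fit without AES replicates 2 and 4 at 48 h was chosen only after the data were seen, and every other setting before. No result reversed its sign past the threshold (0), and a minimum of 1.5-fold kept all 18 counts within 1.5 times. In every setting the median fold change of all probe sets lay within 0.0745 of 0. Its sign could turn, as for ACS against AES at 48 h (−0.034 in the main fit and 0.0521 with centred arrays). Counts that moved are given by setting, and unless stated the cause was not tested.

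With the replicate block the counts were 19, 21 and 16 for AES, AES24h and ACS against IL-1β at 2 h, 696 for IL-1β against control at 48 h, 460, 215 and 246 for the sera at 48 h, 1 for AES24h against AES at 48 h, and 12, 13 and 4 for the differences between times of AES, AES24h and ACS. Arrays of the same replicate number in different groups deviated together at a mean r of 0.126, and those of other numbers at −0.042. Deviations sum to 0 within a group, so the second value largely follows from the first. The mean r of the same number lay between 0.084 and 0.253 in the 14 comparisons. In 5 of them every array of the first group correlated best with its own number, and in the others 2 or 3 of 4 did. All 4 pairs were over 0.1 in 0 of 14 comparisons, so by this rule the numbers were not taken to pair the samples. These values still point to some pairing, and if the numbers mark horses the block counts would be preferred. Of 262 list results 3 passed only with the block (TGF-beta and BMP response with AES at 2 h, adjusted p = 0.0472, fibroblastic genes with ACS at 2 h, 0.0167, and hypoxia and glycolysis with ACS at 48 h, 0.0403).

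With the number as a random effect (consensus correlation 0.079) the counts were 10 and 14 for AES and AES24h at 2 h, 309, 134 and 148 for AES, AES24h and ACS at 48 h, and 4 and 5 for the differences between times of AES and AES24h. With the upper 60% of probe sets they were 0 for AES24h against AES at 2 h, 230 and 109 for AES and AES24h at 48 h, and 4 and 6 for the differences between times of AES and ACS. With quantile normalisation again they were 223 for AES at 48 h and 5 for its difference between times. With centred arrays they were 1 and 4 for AES24h and ACS at 2 h, 87 for AES at 48 h, and 3 and 1 for the differences between times of AES and ACS. With no intensity trend ACS at 2 h had 5. With array weights they were 2260 and 757 for IL-1β at 2 h and 48 h, 9 for AES at 2 h, 146 and 152 for AES24h and ACS at 48 h, and 85 for the IL-1β difference between times. With the spread from only the groups compared, which leaves fewer degrees of freedom, they were 0, 0 and 0 for AES, AES24h and ACS at 2 h, 0 for AES24h against AES at 2 h, 5, 27 and 1 for AES, AES24h and ACS at 48 h, and 3, 0 and 0 for the differences between times of IL-1β, AES and ACS. Without AES replicates 2 and 4, AES at 48 h had 14, from fewer samples.

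Single arrays, and all arrays of 1 replicate number, were left out in turn, fewer samples being tested. Over both, counts at 2 h ranged from 687 to 1303 for IL-1β, 0 to 11 for AES, 0 to 18 for AES24h and 0 to 18 for ACS. They ranged from 0 to 1 for AES24h against AES, and 0 to 0 for ACS against AES and against AES24h. At 48 h they ranged from 130 to 487 for IL-1β, 12 to 328 for AES, 9 to 74 for AES24h, 10 to 103 for ACS, 0 to 134 for AES24h against AES, 0 to 44 for ACS against AES and 0 to 0 for ACS against AES24h. For the differences between times they ranged from 0 to 43 for IL-1β, 0 to 10 for AES, 0 to 3 for AES24h and 0 to 4 for ACS. With only single arrays left out, the lowest counts were 874 for IL-1β at 2 h and 244 at 48 h. They were 25, 17 and 16 for AES, AES24h and ACS at 48 h.

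With shared IL-1β arrays the slopes of return towards control were −0.0978, −0.1115 and −0.0881 at 2 h and −0.004, −0.1697 and −0.1508 at 48 h for AES, AES24h and ACS, by construction lower since both effects then contain the same arrays. With the IL-1β arrays split 2 and 2, the correlations of serum effects were 0.13, 0.1019 and 0.0782 at 2 h and 0.0822, 0.1265 and 0.2347 at 48 h for AES with AES24h, AES with ACS and AES24h with ACS, by construction lower since no array is shared.

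Of 416 named gene results, the threshold was lost and gained by 3 and 19 with array weights, 20 and 2 with centred arrays, 6 and 0 without a trend, 74 and 3 with only the groups compared, 7 and 8 with quantile normalisation again, 0 and 44 with the replicate block and 0 and 26 with the random effect. The upper 60% of probe sets gained 13 of 399, and leaving out AES replicates 2 and 4 lost 15 of 56. Leaving out single arrays or whole replicate numbers in turn lost 565 and gained 51 of 5040. An estimated correlation lost 69 of 262 list results, and the mean of a gene's probe sets changed 0. Values near the lower end of the scale rest on little signal over background, which can shrink fold changes of dim genes.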

Other observations

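The comparison of amino acid genes with chaperones and the simulation of shared signs were chosen only after the results were seen, and the counts over other splits of the arrays before.

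Sterol and fatty acid synthesis genes lay highest in the controls at 48 h. The median of the list was 7.39 to 7.97 on the 4 control arrays, 6.24 to 6.96 with IL-1β, 6.16 to 6.80 with AES, 6.68 to 7.32 with AES24h and 6.73 to 7.16 with ACS. Cell cycle genes varied within groups at 48 h. With ACS their median was 3.74 and 3.96 on replicates 1 and 4, and 5.81 and 6.12 on replicates 2 and 3. With IL-1β it was 4.08 and 4.27 on replicates 1 and 4, and 5.05 and 5.84 on replicates 2 and 3. With AES24h it was 4.26, 5.90, 5.52 and 5.23 on replicates 1 to 4, and with AES 5.32, 4.86, 5.54 and 3.83.

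Markers of other cell types did not pass camera for IL-1β at 48 h, with adjusted p = 0.254 for leukocytes, 0.118 for red cells and platelets, 0.834 for endothelium and mural cells, 0.436 for synovial fibroblasts, 0.223 for bone cells, 0.316 for adipocytes and muscle, and 0.285 for reference genes. CLEC3A, the gene that fell most with the sera, was at −1.94 with IL-1β against control at 48 h and did not pass (adjusted p = 0.182). SRGN, called with AES24h and ACS, was at 1.74 with AES (adjusted p = 0.0545), and the difference between AES and the other sera was not called. Of 199 probe sets called with at least 1 serum at 48 h, 198 (99.5%) had the same sign with all 3. In 100 simulations of unchanged groups that share the IL-1β arrays, 88% of equally many top-ranked probe sets did so on average, and 43.3% to 99.2% over the simulations.

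A hypothesis was that within the unfolded protein and integrated stress response list the amino acid genes, and not the chaperones of the endoplasmic reticulum, fell with the sera at 48 h. The mean difference between the 2 parts was −0.473, sera minus IL-1β (exact permutation p = 0.00934, two-sided, 1820 permutations of 16 arrays, 12 of 12 serum arrays under the IL-1β mean). The 11 amino acid genes had a median of −0.274 with 10 lower, and the 17 chaperones of −0.112 with 14 lower, a difference of medians of −0.161. That lies under the bound of 0.2 set for the opposite outcome. The criteria for and against were thus both met and the hypothesis stays open. It was first marked as excluded, and this was changed after the values were seen. The 2 parts were chosen after results from these same arrays were seen, so the permutation p describes them and is no independent test. By serum the medians of amino acid genes and chaperones were −0.678 and −0.21 with AES, −0.166 and 0.021 with AES24h, and −0.199 and −0.099 with ACS.

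Other splits of the same arrays bear on whether chance can be excluded for the counts of calls. Of the 35 splits of each comparison, only the real 1 gave as many calls for IL-1β at 2 h (1380, highest other 0) and 48 h (386, highest other 27). The same held for AES24h at 2 h (7, highest other 1) and ACS at 2 h (8, highest other 3). It also held for AES at 48 h (135, highest other 8), AES24h at 48 h (69, highest other 10) and ACS at 48 h (80, highest other 56). The smallest share that 35 splits allow is 1 of 35, not adjusted over the comparisons. The splits therefore argue against chance there without excluding it. For AES at 2 h (5, highest other 7, 2 of 35 splits) and AES24h against AES at 2 h (1, highest other 71, 10 of 35) other splits did as well. For the comparisons with a count of 0 in limma the splits test nothing, since each of the 35 gives at least as many. These were ACS against AES and against AES24h at 2 h (highest other 2 and 2; 1313 and 1197 probe sets at an unadjusted p under 0.05), and AES24h against AES, ACS against AES and ACS against AES24h at 48 h (highest other 148, 51 and 19; 3583, 3258 and 756).

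The split with 71 calls for AES24h against AES at 2 h called several times the real count of 1, which points to a structure of the samples. It parted replicates 1 and 4 from 2 and 3 in both groups. The same parting gave 56 calls for ACS against IL-1β at 48 h, under the real count of 80, and 19 for ACS against AES24h at 48 h, where the real count was 0. Real counts of 0 leave chance untested, but the splits with 19, 51 and 148 calls also show arrays that differ within groups. The split with 51 calls put ACS replicates 1 and 4 with AES replicates 2 and 4, and that with 148 put AES replicate 3 with AES24h replicates 1, 2 and 3. For the differences between times, 100 reassignments each gave as many calls in 6 for IL-1β (1, highest other 235), 10 for AES (1, highest other 5), 5 for AES24h (2, highest other 29) and 4 for ACS (2, highest other 4), so chance cannot be excluded for the first 3. For ACS the share lies under 0.05 by 1 reassignment, within the error of drawing 100, so its exclusion is not firm. A reassignment that keeps the groups of 1 time nearly intact retains the effect at that time.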
